A study of Sus scrofa with 6 samples.

How the data were processed

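RNA sequencing was done on jejunum, the middle part of the small intestine, of weaned piglets of a Large White by Landrace cross. The labels place 3 libraries in a control group without transport and 3 in a group that was transported. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with standard Illumina protocols. The labels do not state that the 3 samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical in part. Reads of the Y-linked genes EIF1AY and KDM5D were absent from control 3 and present in the other 5 libraries, so the controls were not all from 1 animal, if labelled correctly. The sex, litter and slaughter day of the piglets, the duration of the journey and the interval before sampling are not given in the sources used here.

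The deposited table holds 24358 Ensembl pig genes with 2 measures per library. Per the file headers, the first is a count per gene and library, deposited by the authors as whole numbers without normalization. Per the file headers, the second is the FPKM, a count scaled to transcript length and library size, as computed by the authors. A gene with a count of 0 is written there with an FPKM of 0.0001. Within a gene the count divided by the FPKM kept a fixed ratio between libraries, with medians of 1 to 1.11 relative to control 1 over 3363 genes with 1 transcript and more than 200 counts in every library, so both columns come from 1 quantification and the counts may be rounded estimates. The aligner, the counting tool, the use of strand and the genome build are not given in the sources used here, and coordinates are printed as the deposited table gives them. All columns with values per sample were matched to a sample. The column names for the transport group carry a prefix that differs from the label, and they were matched by group and replicate number.

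The totals ranged from 48208500 to 53739200 counts per library, so a gene with 100 or more counts has a counting error far below the differences between libraries. Symbols were taken from the table, and 951 of 6907 bare identifiers were given a symbol from a gene name reference. Intervals on count ratios are exact conditional Poisson intervals at 95% and cover counting error only.

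Tests were planned before the data were examined, on the assumption that the table held only FPKM values, with limma on log2(FPKM + 1). Since the table also holds raw counts, the main test became edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, group as the only factor and Benjamini-Hochberg adjustment. The planned limma fit (limma 3.58.1) was kept as an alternative. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, which left 12012 genes. Log2 fold changes are transport against control, with standard errors derived from the quasi-likelihood F statistic. The common biological coefficient of variation was 0.473. Means of FPKM are given with the SD over 3 libraries.

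Gene lists for stress, barrier, immune, enterocyte and epithelial lineage functions, other cell types, gut position and RNA quality were fixed before the data were examined. They were matched by symbol, and 816 of their 946 different symbols, which include aliases, were in the table. A gene held by more than 1 list is counted once there. Of 38 lists, 36 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry's directional test were alternatives. The score of a list in a library is the mean log2 CPM of its tested members (prior count 2), centred over the 6 libraries. Counts of members adjusted over the list alone are given beside those over all genes.

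The rule for named genes was also fixed beforehand. Among genes with a symbol it took, per direction, the 12 with the largest log2 fold change past an adjusted p of 0.05 with a mean FPKM of at least 2 in the higher group. Places left over were filled with the genes of smallest p among those with a log2 fold change of at least 1 in size, the same minimum and no overlap between the groups. It also took up to 4 members per described list with the smallest p, and a fixed set of stress, barrier, inflammation and enterocyte genes regardless of their result. Of the last, HSP90AA1, IL1B and LCT were not analysed here, and CLDN1, IL6 and TNF were among those below the filter. A comparison with a table of the authors' own tests was planned and was not done, as no such table was used here.

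The replicate numbers of the labels were checked for pairing. Deviations from the group mean correlated between libraries of the same number with r = 0.217, 0.111 and 0.187 across genes. Between libraries of different number r ran from -0.261 to 0.101, the highest for control 1 with transport 2. The main fit was unpaired. The labels do not say what a number stands for. A fit with the replicate number as a block was run as an alternative, and its value is printed where it changes a call.

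Alternatives were other filters, median-of-ratios scaling, the replicate block, each library left out in turn, limma on FPKM with other pseudocounts, scalings, variance models and sample weights, and the other list tests. Chosen after the data were seen were the planned limma fit as an alternative, edgeR without scaling between libraries, leaving out both control 2 and transport 3, fry's test without direction, and DESeq2 1.42.0. The scripts were tested on counts simulated from the real means, library sizes and dispersions of the 12012 genes. In these, 200 genes were changed, and the other tested members of the T and NK cell list were raised 2-fold. Of 50 genes per fold size, edgeR recovered 2% at 2-fold, 24% at 4-fold, 80% at 8-fold and 96% at 16-fold, with 3 false calls among 11790 unchanged genes. DESeq2 recovered 22%, 68%, 96% and 100% in the same simulated comparison, with 60 false calls. Figures were drawn with matplotlib.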

Results

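The jejunal transcriptome was compared between 3 samples of piglets taken without transport (controls 1 to 3) and 3 taken after transport (transports 1 to 3). Total counts were 48208500, 49990400 and 50889000 in the controls and 49489500, 51345000 and 53739200 after transport, and 11026 to 12234 genes per library reached an FPKM of 1. Mitochondrially encoded genes took 5.50% to 11.6% of the counts. The libraries did not group by treatment: the mean correlation of log2 CPM across genes was 0.882 within groups and 0.879 between them. Transport 3 stood apart from the rest, with a median correlation of 0.818 with the other libraries against 0.888 to 0.930 for the others, and control 2 was separated on the second principal component, which held 26.5% of the variance.

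The first question was which genes differ in the jejunum after transport. CLDN2, which encodes the pore-forming tight junction protein claudin-2, rose from almost no reads to a well expressed gene. Its FPKM was 0.0264 ± 0.0229 (SD, n = 3) in controls and 67.8 ± 34.8 after transport, from counts of 2, 9 and 4 against 12479, 17659 and 5758. The ratio of summed counts per total was 2308, with a 95% counting interval of 1399 to 4124. The gene ENSSSCG00000037234 lies on the plus strand of chromosome X at 87352488 to 87356443 and overlaps no other gene of the table. In edgeR's quasi-likelihood test its log2 fold change was 11.13 with a standard error of 0.89 and an adjusted p of 0.0314. A second gene, ENSSSCG00000031902, described in the table as uncharacterized and outside the naming rule, was chosen after its values were seen. It rose from 0.00726 ± 0.00279 to 3.83 ± 1.59 FPKM (adjusted p = 0.0248, edgeR). It spans positions 7420983 to 7646448 of the minus strand of chromosome 18 and overlaps 19 other genes there, 9 of them T cell receptor V segments, so its reads are uncertain. Summed over it and those 19 genes, the locus had 75.8 ± 18.9 CPM in controls and 122 ± 28.0 after transport. No gene fell in edgeR's test. At an unadjusted p under 0.05, 423 genes were higher and 193 lower, where 601 in all would be reached by chance, and DESeq2 called 27 higher and 23 lower. Both edgeR calls were lost without control 1, 2 or 3 or transport 1 or 2, where the adjusted p of CLDN2 was 0.169, 0.107, 0.448, 0.159 and 0.126. Without transport 3 there were 3 calls, with GSTO2 added as lower, and the planned limma fit on log2(FPKM + 1) called CLDN2 alone. The log2 fold change of CLDN2 stayed between 10.66 and 11.88 with any 1 library left out.

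**Figure D1:**
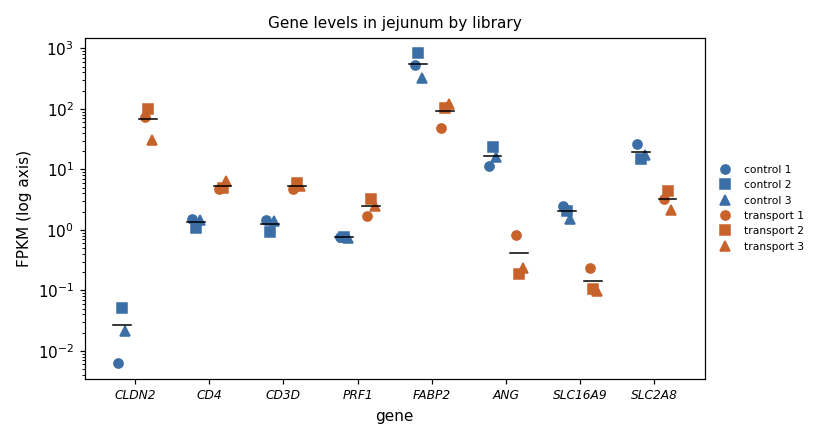
FPKM on a log axis of 8 genes in each of the 6 libraries (blue, control; orange, transport; symbols, replicate number), with a line at each group mean. CLDN2 lies between 0.00627 and 0.0513 in controls and between 31.0 and 100.2 after transport. The groups do not overlap in any gene shown, which the naming rule required of all but CLDN2.

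The other places of the naming rule went to the genes with a symbol of smallest p that had, as the rule required, no overlap between groups. None of them passed the adjusted threshold in edgeR. Among the 11 that were higher after transport were T cell and cytotoxic genes: CD4, the coreceptor of helper T cells, had 1.37 ± 0.243 FPKM in controls and 5.37 ± 0.888 after transport, CD3D, a chain of the T cell receptor complex, 1.26 ± 0.286 and 5.30 ± 0.599, and PRF1, which encodes perforin, 0.751 ± 0.0223 and 2.47 ± 0.745. The desmosomal cadherin DSC3 had 2.0 ± 0.814 and 8.14 ± 2.79 FPKM, and the cell cycle transcription factor E2F3 0.857 ± 0.108 and 6.94 ± 4.72. CYTH4, WBP1L, SH2B2, TRANK1, YAE1 and TMEM104 completed this set, with log2 fold changes from 1.35 to 2.84. Their adjusted p-values in edgeR ran from 0.668 to 0.890.

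The 12 genes that were lower included several of fatty acid handling. FABP2, the intestinal fatty acid binding protein, had 562 ± 255 FPKM in controls and 91.7 ± 38.8 after transport. ACAA2, the mitochondrial thiolase, had 13 ± 0.720 and 4.84 ± 1.19, and SLC25A20, the carnitine-acylcarnitine carrier, 42.9 ± 10.3 and 19.1 ± 3.30. The antimicrobial ribonuclease gene ANG had 16.8 ± 6.06 and 0.412 ± 0.350 FPKM, the solute carrier SLC16A9 2.02 ± 0.491 and 0.145 ± 0.0752, and the glucose transporter gene SLC2A8 19.4 ± 5.90 and 3.26 ± 1.16. EPHB2, a receptor of the crypt, had 10.7 ± 3.66 and 3.08 ± 1.38, and COX17, a copper chaperone of cytochrome oxidase, 125 ± 26.1 and 53.7 ± 19.4. MOV10L1, CGREF1, CELSR1 and TMEM164 had log2 fold changes of -5.37, -3.26, -1.60 and -1.74. Adjusted p-values of the 12 ran from 0.459 to 0.890 in edgeR. DESeq2 called 9 of the 11 higher genes and 11 of these 12, all except CYTH4, TRANK1 and COX17, and another split of the same 6 libraries, which parts 1 of the 3 pairs of equal number, gave it 141 genes. The 3 other splits that part all 3 pairs gave it 5, 9 and 34. Genes without overlap between the groups numbered 1336, or 11.1% of those tested, where chance gives 10%. By the looser rule of an unadjusted p under 0.05 and a 2-fold change, 329 genes were higher and 132 lower, and 102 and 145 after quantile normalization with limma.

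Gene lists fixed beforehand addressed which cell types and functions moved. By camera with a preset correlation, 7 lists were higher and 11 lower, and no list passed with an estimated correlation or with fry's directional test. Fry's test without direction passed the tight junction (adjusted p = 3.82e-05) and T and NK cell (0.0096) lists. The tight junction list holds CLDN2, the gene already called, and the test was not repeated without it. The lists were described on the same 6 libraries, of which transport 3 carried ileal and B cell genes and control 2 little smooth muscle RNA.

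The T and NK cell list was the one most clearly higher. All 24 tested members had higher values after transport, 19 of them without overlap between the groups, and the median log2 fold change was 0.95 (camera adjusted p = 1.21e-19; adjusted p = 0.190 with an estimated correlation). No member passed over all genes tested, and 4 passed adjusted over the list alone: CD4, CD3D and PRF1, and LCK, the T cell receptor kinase, at 2.66 ± 0.242 and 10.7 ± 8.29 FPKM. The list score was between -0.73 and -0.36 in the controls and between 0.34 and 0.74 after transport. The median was 1.0 without transport 3 and 0.99 without control 2.

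The interferon, antigen presentation, inflammation and B cell lists were higher as sets, with no member past the threshold over all genes or over the list alone. In that order, 1 of 30, 4 of 15, 2 of 20 and 1 of 11 members were higher without overlap between the groups. The scores of all 4 lists overlapped between the groups. For interferon, control 3 was at 0.565 against 0.256 and 0.0742 in transports 1 and 3. The myeloid cell list did not pass (median 0.37, camera adjusted p = 0.146), except without control 3 (0.00302, median 0.54). Its median was 0.15 without control 2 and 0.19 without transport 2. In the interferon-stimulated list 28 of 30 members had higher values (median 0.58, camera adjusted p = 2.25e-05; adjusted p = 0.591 with an estimated correlation). IRF9, part of the interferon-activated transcription complex, had 18.8 ± 7.46 and 43.7 ± 11.6 FPKM, STAT2 of the same complex 21.8 ± 4.35 and 44.6 ± 18.3, and the antiviral RSAD2 7.42 ± 8.85 and 26.4 ± 14.6, with 17.6 in control 3. The median of that list was 0.36 without control 1 or control 2, 1.23 without control 3 and 0.30 without transport 2. In the antigen presentation list 11 of 15 were higher (median 0.59, camera adjusted p = 0.00605; adjusted p = 0.539 with an estimated correlation), with NLRC5, the class I transactivator, at 4.14 ± 1.04 and 7.93 ± 1.31 and CIITA, the class II transactivator, at 2.01 ± 0.921 and 6.28 ± 4.54. Without transport 2 its adjusted p was 0.319. In the inflammation list 14 of 20 were higher (median 0.51, camera adjusted p = 0.0388; adjusted p = 0.539 with an estimated correlation), among them CXCL10, a chemokine that attracts T cells, at 5.18 ± 2.45 and 30.1 ± 24.2, and NFKB2 at 11.8 ± 1.65 and 23.0 ± 6.05. That call was lost with the replicate block (adjusted p = 0.0533), without control 1 (0.276) and without transport 2 (0.431), and the median was 0.31 without control 2 and 0.10 without transport 3. CXCL8, the neutrophil chemokine, had 19.5 ± 15.2 and 15.5 ± 11.7 FPKM. The B and plasma cell list had a median of 1.08 with 9 of 11 higher (camera adjusted p = 0.0045; adjusted p = 0.539 with an estimated correlation). It was 0.32 without transport 3 and 1.66 without control 3, and the call was lost without control 1 (adjusted p = 0.184). The median depended on the filter, at 3.84 with none and 5.07 with a mean FPKM of at least 5. CD79B, part of the B cell receptor, was at 186 FPKM in transport 3 and at 0.934 to 2.97 in the other 5 libraries.

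Genes of lipid absorption were lower as a set: 15 of 22 members, with a median of -0.72 (camera adjusted p = 1.00e-07; adjusted p = 0.539 with an estimated correlation). Of the 22, 5 were lower without overlap between the groups. The list scores overlapped, with transport 2 (0.579) above control 3 (0.112). FABP2 passed adjusted over the list alone. The apolipoprotein genes APOC3 and APOA4 had 2504 ± 1349 and 326 ± 233 FPKM, and 926 ± 166 and 148 ± 129, and FABP1, the liver-type fatty acid binding protein, 2601 ± 654 and 729.6 ± 525, none with overlap between groups. Transport 3, with its ileal genes, had the lowest score of this list, and the median was -0.43 without it, -0.20 without control 2 as well, and -1.17 without transport 2. The fatty acid oxidation list was also lower (median -0.17, 15 of 24 members, camera adjusted p = 0.014; adjusted p = 0.714 with an estimated correlation), and its members went both ways: adjusted over the list alone, ACAA2 and SLC25A20 fell, while ANGPTL4, an inhibitor of lipoprotein lipase, had 16.2 ± 6.24 and 44.4 ± 13.2 FPKM and the mitochondrial carrier gene UCP2 10.9 ± 2.09 and 87.1 ± 123, its mean carried by transport 3 (13.2, 19.4 and 229 in transports 1 to 3). Its call was lost without control 1 (0.0943), control 2 (0.0579), transport 1 (0.0842) or transport 3 (0.424), with medians of -0.49 without transport 2 and -0.04 without transport 3. Cholesterol synthesis genes were lower in 19 of 23 members (median -0.40, camera adjusted p = 2.39e-05; adjusted p = 0.539 with an estimated correlation). Here 6 members were lower without overlap, and transport 2 (0.131) scored above control 3 (0.0665). NSDHL had 10.9 ± 2.04 and 5.49 ± 0.732 FPKM, MVK, mevalonate kinase, 5.71 ± 1.02 and 2.85 ± 0.821, and IDI1 54.5 ± 5.88 and 33.5 ± 4.06.

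Brush border digestive enzymes were higher in 15 of 17 members (median 0.84, camera adjusted p = 0.00666; adjusted p = 0.714 with an estimated correlation). ANPEP, aminopeptidase N, had 525 ± 101 and 1070 ± 438 FPKM, MGAM, maltase-glucoamylase, 57.7 ± 5.45 and 145 ± 113, SI, sucrase-isomaltase, 27.3 ± 20.8 and 73.6 ± 44.9, and XPNPEP2 1.31 ± 0.573 and 31.3 ± 45.1, its mean carried by transport 3 (1.23, 9.61 and 83.1 in transports 1 to 3). Transport 1 (-0.540) scored below controls 1 (0.186) and 2 (-0.352). Transport 2 had the highest score of the list. Without it the call ended (adjusted p = 0.675, median 0.12, camera direction turned), as it did without control 3 (adjusted p = 0.147). The glucose transporter SLC5A1 had 91.1 ± 52.2 and 131 ± 79.5 FPKM and the peptide transporter SLC15A1 33.3 ± 10.1 and 68.4 ± 63.0, with overlap between groups and 140.5 for SLC15A1 in transport 2.

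Genes of protein folding in the endoplasmic reticulum were lower. Of 23 members of the endoplasmic reticulum stress list, 18 had lower values, 10 of them without overlap, with a median of -0.61 (camera adjusted p = 2.29e-11; adjusted p = 0.539 with an estimated correlation). None passed over all genes tested, and 4 fell adjusted over the list alone. HSPA5, the chaperone BiP, fell from 348 ± 118 to 144 ± 33.4 FPKM, CALR, calreticulin, from 539 ± 155 to 209.9 ± 40.6, DNAJB11 from 45.5 ± 13.3 to 19.2 ± 2.84, and XBP1, a transcription factor of secretory cells, from 71.2 ± 23.0 to 28.4 ± 9.41. The median was -1.07 without transport 2.

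Lists of secretory and crypt cells were lower too, but their scores overlapped between the groups. Control 1 lay below transport 1 in the goblet cell (-0.570 against 0.269), antimicrobial (-0.206 against -0.0732) and stem and tuft cell (0.137 against 0.288) lists. For ion and water secretion, control 2 (-0.0824) lay below transports 1 and 2 (0.118 and 0.229). Of the 10 goblet cell genes, 1 was lower without overlap. All 10 goblet cell genes had lower values (median -0.79, camera adjusted p = 0.000374; adjusted p = 0.539 with an estimated correlation), with 22.0 ± 7.48 and 7.35 ± 2.42 FPKM for CREB3L1 and 123 ± 60.0 and 65.6 ± 33.1 for MUC2, the main intestinal mucin. Its median was -1.22 without control 1, -1.26 without transport 1 and -0.52 without transport 3, and the call was lost without both control 2 and transport 3 (adjusted p = 0.570). In the antimicrobial list 5 of 7 were lower (median -1.44, camera adjusted p = 0.00046; adjusted p = 0.539 with an estimated correlation): LYZ, lysozyme, had 2540 ± 1442 and 336 ± 389 FPKM, BPI 130 ± 87.9 and 8.72 ± 7.53, while NOS2, inducible nitric oxide synthase, had 2.36 ± 1.81 and 8.50 ± 7.08. The median was -0.87 without control 3 and -2.17 without transport 1. The stem and tuft cell list had 10 of 15 lower (median -0.46, camera adjusted p = 0.00046; adjusted p = 0.539 with an estimated correlation), with EPHB2 past the threshold adjusted over the list alone, and OLFM4, a crypt base marker, at 1891 ± 1288 and 382 ± 247 FPKM. The median was -0.24 without control 1, -0.82 without transport 1 and -0.27 without transport 3. It was -1.53 with a mean FPKM of at least 5, and the call was lost with sample weights (adjusted p = 0.0889). In the ion and water secretion list 15 of 19 were lower (median -0.43, camera adjusted p = 0.00562; adjusted p = 0.539 with an estimated correlation). CFTR, the chloride channel, had 8.59 ± 1.31 and 4.19 ± 2.0 FPKM and the channel subunit KCNE3 23.3 ± 4.80 and 9.16 ± 5.11. The median was -0.28 without control 1 or transport 3 and -0.66 without transport 2, and the adjusted p was 0.0753 without transport 3.

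**Figure D2:**
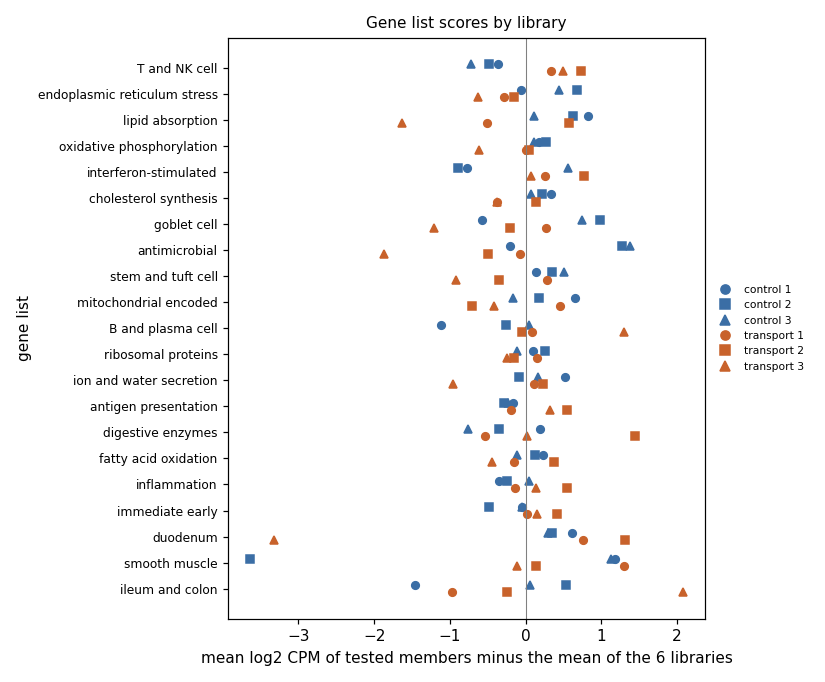
Scores of 21 gene lists in each library, as the mean log2 CPM of the tested members minus the mean of the 6 libraries, for the 18 lists past the camera threshold and 3 lists of position and muscle. The T and NK cell scores of all 3 transport libraries lie above those of all 3 controls, while control 2 is far below the rest in smooth muscle and transport 3 in the duodenum list.

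Genes of energy metabolism and translation were slightly lower. The oxidative phosphorylation list had 37 of 39 members lower with a median of -0.33 (camera adjusted p = 7.49e-07; adjusted p = 0.591 with an estimated correlation), for example NDUFV2 of complex I at 16.8 ± 0.996 and 12.5 ± 0.941 FPKM. Its median was -0.18 without transport 3, and the call was lost without both control 2 and transport 3 (adjusted p = 0.138). The 13 mitochondrially encoded genes were all lower (median -0.41, camera adjusted p = 0.00409; adjusted p = 0.714 with an estimated correlation), with COX3 at 20281 ± 3889 and 15487 ± 4089 FPKM. All 13 overlapped between the groups. Transport 1 had the largest mitochondrial share of the libraries (11.6%), and its list score of 0.458 exceeded those of controls 2 (0.171) and 3 (-0.162). The call of the list was lost without control 1 (adjusted p = 0.155, median -0.20) and without transport 2 (0.264, -0.19), and the median was -0.80 without transport 1. It was also lost after quantile normalization (0.0828), with sample weights (0.225) and without both control 2 and transport 3 (0.0724). Ribosomal protein genes were lower in 51 of 56 members by a median of -0.17 (camera adjusted p = 0.00457; adjusted p = 0.891 with an estimated correlation), and after quantile normalization the direction turned, with a median of 0.08. RPS27A had 538 ± 34.4 and 465 ± 17.4 FPKM. The call was lost without control 2 (0.277, median -0.08), transport 2 (0.0725) or transport 3 (0.0833), and the median was -0.31 without transport 1 and -0.26 without control 3.

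The stress response to transport was addressed by lists of heat shock, glucocorticoid and immediate early genes. The immediate early list was higher in 15 of 16 members (median 0.38, camera adjusted p = 0.0434; adjusted p = 0.539 with an estimated correlation), with EGR1 at 4.83 ± 2.51 and 9.09 ± 0.894 FPKM and FOS at 12 ± 3.82 and 22.9 ± 11.7. That call was lost without control 1 (0.0585), control 2 (0.146), transport 1 (0.0598) or transport 2 (0.389). The heat shock list did not pass (median -0.18, camera adjusted p = 0.0697), but did without control 2 (0.0136) or transport 3 (0.00324, median -0.37), without both (0.000609, median -0.42) and with sample weights (0.0122). Its median was nearer 0 without control 3 (-0.05) or transport 1 (-0.07). HSPA1A, HSPA1B, HSPA6 and HSP90AA1 were not matched by symbol, so the heat shock result does not cover them. HSPA8, the constitutive chaperone, had 178 ± 24.1 and 156 ± 43.7 FPKM, HSPH1 23.1 ± 2.76 and 25.7 ± 16.2, and the mitochondrial chaperonin gene HSPE1 518 ± 64.7 and 397 ± 85.3. The glucocorticoid response list did not pass either (median -0.25, camera adjusted p = 0.171), except without control 3 (0.0373, median -0.46), and its direction turned without control 1. FKBP5, a glucocorticoid receptor target, had 20.1 ± 15 and 11.3 ± 1.55 FPKM, with 5.56, 35.5 and 19.2 in controls 1 to 3. With 1 library left out, its log2 fold change ran from -1.35 to -0.135. TSC22D3 had 30.2 ± 26.2 and 25.0 ± 18.1 FPKM, and the clock gene PER1 18.0 ± 4.44 and 8.21 ± 4.66. Of the 16 tested members of the glucocorticoid list, 5 had higher values. Among these was MT1A, with 55.7 ± 93.6 and 565 ± 242 FPKM and no overlap between groups. The mean log2 fold change of the list was -0.04. Of the antioxidant enzymes, SOD1 had 232 ± 11 and 241 ± 89.6 FPKM, SOD2 26.2 ± 3.70 and 31.7 ± 12, and CAT, catalase, 33.2 ± 8.69 and 66.9 ± 72.6, each with overlap between groups and 150.2 for CAT in transport 2.

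Among 19 tight junction genes only CLDN2 rose, over all genes tested and adjusted over the list alone, and none fell by either adjustment in edgeR. CLDN3 had 212 ± 56.0 FPKM in controls and 102 ± 63.4 after transport, CDH1, E-cadherin, 115 ± 29.4 and 51.3 ± 11.2, TJP1, the scaffold ZO-1, 8.71 ± 1.10 and 14.1 ± 8.80, and OCLN, occludin, 16.1 ± 1.83 and 14.3 ± 8.75. The TJP1 mean after transport was carried by transport 3 (8.94, 9.06 and 24.2 in transports 1 to 3). As a set the list did not pass (median -0.07, camera adjusted p = 0.887), and the median and mean, 0.44, differed in sign because of CLDN2. Without transport 3 the set passed as higher (median 0.11, adjusted p = 0.0129) and without transport 2 as lower (median -0.57, 0.00711).

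Markers of gut position and of other cell types differed between single libraries more than between groups. Transport 3 had 6836 FPKM of FABP6, the ileal bile acid binding protein, against 2.83 to 13.8 in the other 5, and 314 of TMIGD1 against 0.771 to 4.32. GATA4, a transcription factor of the proximal intestine, was at 0.906 FPKM in transport 3 and 44.4 to 59.5 elsewhere. The ileum and colon list had a median of 0.52 (camera adjusted p = 0.485), and of -0.29 without transport 3, and passed without control 2 (0.0275, median 0.87). The duodenum list had a median of 0.15 against a camera direction of lower (adjusted p = 0.203), and passed as higher without transport 3 (0.00238, median 0.43) and as lower without transport 2 (0.00705, median -0.57). Control 2 had 8.56 FPKM of MYH11, smooth muscle myosin, against 199.9 to 643 in the other 5 libraries, and 3.86 of ACTG2 against 197 to 612. The smooth muscle list (median -0.04 against a camera direction of higher, adjusted p = 0.384) passed as higher with the replicate block (0.0407), as did that of enteric neurons and glia (0.0348 against 0.316 without it). The latter passed as higher without control 1 too (0.00424, median 1.11) and turned without control 2 (median -0.31). Smooth muscle also passed as lower without control 2 (5.22e-05, median -0.59) and as higher without control 1 (0.00809) or control 3 (0.00516). Cell proliferation genes had a median of 0.58 (camera adjusted p = 0.426), and -0.57 without transport 3 (2.42e-07), since that library held 82.2 FPKM of TOP2A, topoisomerase 2 alpha, against 5.64 to 15.5 in the others. They passed as higher without transport 2 (0.000392, median 0.96). Without passing, the direction of the proliferation list and of the ileum and colon list turned without control 1, and that of smooth muscle without transport 1. The fibroblast and endothelium list had a median of 0.08 (camera adjusted p = 0.683), and passed as lower without control 2 (0.003, median -0.36) and as higher without control 3 (0.0193, median 0.40). Of the other lists that did not pass, xenobiotic metabolism (median 0.65, camera adjusted p = 0.164), autophagy (0.25, 0.061) and the circadian clock (0.15, 0.699) passed as higher without transport 3 (2.01e-08, 0.00775 and 0.0242). Xenobiotic metabolism also passed without control 1 (0.000228) and turned without transport 2 (median -0.21). Autophagy passed without control 2 (0.0396) and with the planned limma fit (0.0217), but its median was 0.095 without transport 2 (camera adjusted p = 0.502). The circadian clock turned without control 2, transport 1 or transport 2.

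**Figure D3:**
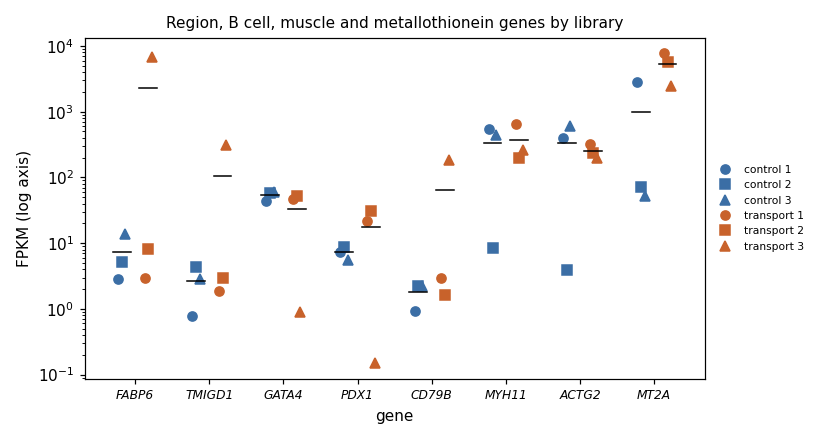
FPKM on a log axis of 8 genes of gut position, B cells, smooth muscle and metal binding in each of the 6 libraries, with a line at each group mean. Transport 3 alone is high in FABP6, TMIGD1 and CD79B and low in GATA4 and PDX1, and control 2 alone is low in MYH11 and ACTG2.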

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

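The planned limma fit as an alternative, edgeR without scaling between libraries, leaving out both control 2 and transport 3, fry's test without direction, and DESeq2 were chosen after the data were seen; the other alternatives were not. Where a value changed, the cause was not tested unless fewer genes or samples are named. The 2 genes called by edgeR kept their call with no filter, median-of-ratios scaling, the replicate block and no scaling. The count was 1, CLDN2, with a mean FPKM of at least 5 (fewer genes tested), without both control 2 and transport 3 (fewer samples), and with limma on log2(FPKM + 1), with a pseudocount of 0.1, rescaled to an equal sum, without trend, robust, or with sample weights. With quantile normalization it was 2, CLDN2 and ANG. Leaving out 1 library gave 0 to 3, and DESeq2 50. Over all alternatives the adjusted p of CLDN2 ran from 1.11e-47 to 0.448, and its log2 fold change was above 5 in each. The looser count of 461 was 719 with no filter and 297 with a mean FPKM of at least 5. In limma it was 252, 255 without trend, 249 robust, 218 with sample weights and 247 after quantile normalization. It was 298 without both control 2 and transport 3, and 231 to 826 with 1 library left out. Of its genes 71.4% were higher in the main count; the limma splits of higher and lower were 141 and 111 as planned, 209 and 139 with a pseudocount of 0.1, 102 and 145 after quantile normalization. The 18 lists became 0 with an estimated correlation and 0 with fry's directional test (2 with its test without direction), and 16 to 22 elsewhere. Of the 18, 11 were shared with sample weights and 11 without both control 2 and transport 3, 12 without transport 2, 13 without control 1, 15 without control 2 or transport 3, and 16 to 18 under the others. With sample weights the lists lost were stem and tuft cell, mitochondrially encoded, ribosomal, antigen presentation (adjusted p = 0.0591), digestive enzymes (0.232), inflammation (0.18) and immediate early (0.0667). Without both libraries they were oxidative phosphorylation, goblet cell, mitochondrially encoded, ribosomal, ion and water secretion (0.0972), fatty acid oxidation (0.779) and immediate early (0.0957). Gained with sample weights were heat shock (lower, 0.0122), cell proliferation (lower, 0.0353), smooth muscle (higher, 0.0353), xenobiotic metabolism (higher, 0.00303) and autophagy (higher, 0.0353). Gained without both libraries were heat shock (lower, 0.000609), cell proliferation (lower, 0.000123), smooth muscle (lower, 0.0144), fibroblasts and endothelium (lower, 0.0347), tight junction (higher, 0.00348), duodenum (higher, 0.00398), xenobiotic metabolism (higher, 3.91e-08), autophagy (higher, 0.00578) and hypoxia (higher, 0.0483). The inflammation call was lost with no filter (0.114), with a mean FPKM of at least 5 (0.0613) and in the planned limma fit (0.0553). The antimicrobial median was -0.93 with no filter, -2.29 with a mean FPKM of at least 5 and -0.61 with sample weights. The replicate block called 19 lists, 17 of them shared, and besides the inflammation, smooth muscle and enteric neuron lists it changed no other call of a gene or list. No scaling moved the median log2 fold change of all genes by over 0.1.

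Direction turned mostly in results that were not called over all 6 libraries, though lists named above as gained passed in the turned direction. With the replicate block these were HSPH1 (-0.10), SOD1 (-0.074) and, for the list test, tight junction (median -0.14). HSPH1 was also at -0.031 with a pseudocount of 0.1, -0.057 after quantile normalization, -0.023 in limma as planned, robust or without trend, -0.24 with sample weights and -0.54 without both libraries, against 0.04. SOD1 was at -0.0068 with limma as planned, robust or without trend, -0.0071 with a pseudocount of 0.1 and -0.022 with sample weights. With sample weights SLC5A1 was at -0.049, TSC22D3 at 0.14, and the medians of cell proliferation, ileum and colon, and duodenum at -0.18, -0.22 and 0.13. Without both control 2 and transport 3, TJP1 was at -0.017, CXCL8 at 0.23, OCLN at 0.084, and the medians of tight junction, smooth muscle, cell proliferation, duodenum, enteric neurons, and fibroblasts and endothelium at 0.13, -0.28, -0.48, 0.48, -0.18 and -0.27. The called list of ribosomal proteins turned to 0.084 after quantile normalization, and fry turned the direction of tight junction, whose median is -0.071.

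With 1 library left out, the following medians ran across a change of direction: digestive enzymes 0.12 to 1.25, glucocorticoid response -0.60 to -0.027, tight junction -0.57 to 0.13, smooth muscle -0.62 to 0.28, cell proliferation -0.57 to 0.96, ileum and colon -0.29 to 0.87, duodenum -0.57 to 0.70, enteric neurons -0.41 to 1.11, fibroblasts and endothelium -0.36 to 0.40, xenobiotic metabolism -0.21 to 1.08, and circadian clock 0.012 to 0.37. Where median and range share 1 sign, it was the list test that turned. Single genes ran from -1.17 to 0.29 (CXCL8), -0.51 to 0.34 (HSPH1), -0.20 to 1.42 (SLC15A1), -0.14 to 0.92 (SLC5A1), -0.49 to 1.48 (CAT), -0.41 to 0.21 (SOD1), -0.90 to 0.11 (OCLN), -1.09 to 0.70 (TSC22D3) and -0.19 to 0.45 (SOD2).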

Other observations

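All tests of explanations in this part were chosen after the results they address were seen, and the genes of the next 2 paragraphs were chosen after their values were seen.

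Metallothioneins, small proteins that bind zinc and copper, differed widely between libraries. MT2A had 2862, 72.7 and 52.3 FPKM in controls 1 to 3 and 7759, 5771 and 2443 in transports 1 to 3. MT1A had 164, 1.37 and 2.02 against 640, 760 and 294, and MT3 33.3, 1.18 and 2.28 against 314, 532 and 97.1. These neighbours on chromosome 6 have similar sequences, and reads shared between them were not examined. SLC39A4, which takes up zinc from the gut lumen, had 22.4, 41.2 and 41.6 against 6.59, 8.99 and 1.68 FPKM. Each of the 4 had an adjusted p of 0.890 in edgeR, and DESeq2 called MT3 and SLC39A4.

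The regenerating islet-derived gene ENSSSCG00000031177 had 23.4, 4323 and 2150 FPKM in the controls and 27.2, 84.0 and 10.8 after transport (adjusted p = 0.890 in edgeR, 0.00336 in DESeq2). Another gene, ENSSSCG00000037620, overlaps it on the other strand. LYZ had 877, 3296 and 3447 against 785, 142 and 82.4, so control 1 lay near transport 1 in both antimicrobial genes. HBB, a chain of haemoglobin, had 35.1, 11.6 and 21.1 FPKM against 102, 123 and 45.3 (adjusted p = 0.890, edgeR).

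With 6 libraries there are 10 splits into groups of 3, too few for a share under 0.05. Of these, 1 gave at least 2 genes past the adjusted threshold (the real split; highest other 1), 3 gave at least 461 by the looser rule (highest other 592) and 5 gave at least 18 lists (highest other 21). Genes with at least 1 FPKM throughout 1 group and at most 0.05 throughout the other numbered 3 in the real split. CLDN2, at 0.0513 in control 2, falls outside that rule. The split of control 1, transport 1 and transport 3 against the rest also gave 3. The split that set control 1, transport 1 and transport 2 against the rest gave 592 genes, and 141 by DESeq2 against 50, which points to a structure of the samples other than the groups. Of the 4 splits that part all 3 pairs of equal number, the 3 others gave 0 genes each, 120 to 324 by the looser rule and 10 to 20 lists, and DESeq2 gave 5 to 34.

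A first pattern was the rise of CLDN2 and ENSSSCG00000031902. CLDN2 lies on the X chromosome, but a difference in sex between the groups is argued against: the highest CLDN2 value of a control library with reads of Y-linked genes was 0.00166 times the lowest after transport, and 5 of the 6 libraries had such reads. For ENSSSCG00000031902, the genes that overlap it had 75.7 CPM in controls and 96.2 after transport, a ratio of 1.27, where reads moved from them alone would lower that sum. The difference lay within a spread of 20.8 CPM, so a shift of reads between overlapping models is neither shown nor excluded. An effect of transport is a hypothesis that stays open for both genes.

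A second pattern was the higher T and NK cell list. Its median of 0.95 was reached by 1 of the 10 splits, the real one, with 0.58 as the highest other, and too few splits exist for a share under 0.05. Neither lymphoid tissue in transport 3 nor the little muscle in control 2 accounts for it, since the median was 1.0 without the former and 0.99 without the latter. A lower share of epithelial cells may contribute: the group difference of the T and NK cell score exceeded that of the fibroblast and endothelium score by 0.70, against a spread of 0.99, which leaves that open over all 6 libraries. Without control 2 it was 1.45 against a spread of 0.408, and the fibroblast and endothelium list was lower (median -0.36, camera adjusted p = 0.003), which argues against it in those 5; without transport 1 it was 0.95 against 0.938, and with any other library left out 0.20 to 0.60, within the spread. More T cells after transport is a hypothesis, as is tissue sampled closer to lymphoid aggregates, and neither was tested. HBB was higher too, without overlap between the groups, and a larger share of blood was not tested either.

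The last pattern was the ileal and B cell genes of transport 3. For gut position, an effect shared by all 3 transport libraries was not seen in transports 1 and 2, but it is not excluded. Without transport 3 the duodenum list was higher (median 0.43, camera adjusted p = 0.00238), where such an effect would lower it. The ileum and colon list then had a median of -0.29 (camera adjusted p = 0.288), and without control 2 as well 0.27. An effect in transport 3 alone cannot be told apart from other properties of that sample. For B cell genes an effect of transport stays open, as their list was higher without transport 3 (median 0.32, camera adjusted p = 0.0345). CD79B had 2.97 and 1.63 FPKM in transports 1 and 2 against 0.934 to 2.24 in controls, and MS4A1 and PAX5 overlapped between them too. Ileal RNA added to a jejunal sample is argued against, since the larger of GATA4 and PDX1 was 0.0271 times its lowest value elsewhere. A piece of gut taken further down stays possible. The ileum and colon score was 1.55 above the highest of the other 5 libraries, and the duodenum score minus the lowest of theirs was -3.61. Those lists hold FABP6, GATA4 and PDX1, which define the pattern, so the scores restate it and lend this explanation no support. A swap with a sample outside the series was not tested.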
